A study of Rattus norvegicus with 12 samples.

How the data were processed

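Small RNA was measured in primary cortical neurons of Sprague Dawley rats, taken at embryonic day 17 and plated at 100000 cells per square centimetre. Per the labels' protocols, the neurons received lentivirus at 10 days in vitro and were lysed at 14 days in vitro. The virus carried a short hairpin RNA (shRNA) that is non-targeting (shNTC), targets Stau2 (shStau2) or targets Pum2 (shPum2). Stau2 encodes Staufen2, a protein that binds double-stranded RNA, and Pum2 encodes Pumilio 2, a protein that binds single-stranded motifs in mRNAs. Each of the 3 groups had 4 libraries, which the labels call biological replicates and number 1 to 4. Whether a number stands for the same neuron preparation is not given in the sources used here. RNA was isolated as a batch with a miRNeasy kit and had an RNA integrity number of 9.5, per the labels' protocols.

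The deposited values were whole-number counts per small RNA name, with a separate table for each library, and were not normalised. Libraries were made with a kit that adds unique molecular identifiers, per the labels' protocols. Whether the deposited counts are molecules or reads, and which aligner and counter produced them, is not given in the sources used here. The genome build was Rnor 6.0, per the submitters' processing notes. If reads and not molecules were counted, copies made by amplification would add to the apparent depth, so intervals and floors from counts cover counting error only. The tables held 805 small RNA names, 685 of miRNAs and 120 of Piwi-interacting RNAs (piRNAs). For 7 miRNA names the authors' table combined several miRNAs. Members of a family with nearly identical sequences, such as those of miR-29 or let-7, may have exchanged reads in the authors' assignment, and their separate values are uncertain to that extent. No strand or position was used here.

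Totals per library lay between 3836349 and 5415763 counts. A floor of 3 counts corresponded to 0.558 to 0.788 CPM, depending on the library, and between 653 and 662 miRNA names had at least 1 count. The miRNAs were tested with edgeR 4.0.16 in R 4.3.3: trimmed mean of M-values (TMM) scaling, the filterByExpr filter by group, and the quasi-likelihood test with robust estimation, with all 12 libraries in a joint fit by group. The filter left 628 of the 685 miRNA names and removed 57. P-values were two-sided, Benjamini-Hochberg adjusted over the miRNAs tested, and called at an adjusted p of 0.05 without a minimum fold. Levels are TMM-scaled CPM, given as mean ± SD with n = 4 per group. Log2 fold changes are followed by their standard errors (SE). The values are shares of a library, so they show relative levels and not amounts per cell. The 90 piRNA names that passed the same filter were tested in a further fit that also held the miRNAs. Their p-values were adjusted over the miRNAs and piRNAs of that fit together.

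Before the data were examined, 18 lists of miRNAs were fixed. They held neuron-enriched miRNAs, miRNAs linked to neuronal activity or dendrites, the Dlk1-Dio3 cluster, the let-7 family, the miR-17 cluster with its paralogs, the miR-183, miR-96 and miR-182 cluster, and the miR-200, miR-29, miR-30 and miR-181 families. Further lists held p53-responsive miRNAs, miRNAs subject to target-directed decay, miRNAs that bypass Drosha or Dicer, and markers of oligodendrocytes, astrocytes, blood or microglia, vessels or mesenchyme, and choroid or ciliated cells. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01 on log2 CPM with a prior count of 2, adjusted over the lists. The estimated correlation was run beside it, and so was fry, whose directional test asks whether a list moves on balance in a direction by itself and whose mixed test asks whether members differ in either direction. Some miRNAs stand in more than 1 list, for example 2 of the 14 astrocyte miRNAs, 3 of the 9 decay miRNAs and 6 of the 11 choroid or ciliated miRNAs.

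Also fixed before the data were examined were the comparisons, the model, the alternatives and the rule for naming miRNAs. The rule took, per comparison, up to 12 miRNAs higher and 12 lower with the smallest p among those past the threshold with a mean of at least 10 CPM, or the 5 with the smallest p where fewer than 5 passed. It added the 5 most abundant miRNAs, the 2 most abundant members of each list, and list members past the threshold. Applying the same rule to the fit with a replicate block was chosen after seeing the data. So was naming the calls outside the rule among the miRNAs that passed against both controls, and the arm partners miR-29c-3p and miR-29c-5p.

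Libraries were checked for pairing by replicate number, through correlations across miRNAs of their deviations from the group means. For the 12 same-number pairs r lay between 0.36 and 0.57, all above the 0.1 set as the limit. For the 36 other pairs from different groups it lay between -0.41 and 0.14, and 12 of 12 libraries correlated best with a library of their own number. The numbers were therefore taken to pair the libraries. This rests on the data, since the labels do not say what a shared number means. The fit with the number as an added term (replicate block) was planned as an alternative, and its values are given beside the results whose calls or counts it changed. It lowered the median SE from 0.169 to 0.119.

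Other alternatives were median-ratio, upper-quartile and total-count scaling, no filter and a filter at a mean of 10 CPM, DESeq2 1.42.0, fits on the 8 libraries compared, the 5 most abundant miRNAs left out, thinning to the smallest library, an adjusted p of 0.1, and leaving out each library. The same alternatives within the replicate block, and a table that kept the piRNAs, were chosen after seeing the data. Counts from replicates of a group differed by far more than sampling noise (chi-square over degrees of freedom 29.8 to 85.2). A repeat library of the same RNA could exceed sampling noise too, so this does not show that the replicates are separate samples. They were taken as biological replicates because the labels call them so. Group differences in depth measures were compared with exact two-sided permutation tests.

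The procedure was tested on data simulated with the library sizes and with the means, replicate effects and spread that the fit with the block estimated. In 10 simulations, 200 of 628 miRNAs were changed in a group standing for shStau2, and a mean of 619 passed the filter and were tested. For shStau2 against shNTC without the block, 11.8% of changes of 1.25-fold, 54.6% of 1.5-fold and 82.6% of 2-fold were recovered, and 0.101% of calls were false. With the block the shares were 45.5%, 80.9% and 93.6%, and 3.87% of calls were false. The simulated libraries followed the model of the block, so its gain in recovery and its share of false calls are partly built in. A mean of 99.1 miRNAs was called without the block and 152 with it, against 2 and 39 in the real libraries. More calls loosen the adjusted threshold, so recovery in the real libraries may be lower than simulated. A seeded list of 20 miRNAs was found in 10 of 10 simulations, and 1.67% of unchanged lists were called with the preset correlation against 0.556% with the estimated correlation. The simulations drew each miRNA independently, so these shares do not hold for lists whose members vary together. In the real libraries the miR-29 family had an estimated correlation of 0.46. Other splits of the real shStau2 and shNTC libraries gave up to 8 lists with the preset correlation. Gene names and neighbours came from a table of assembly GRCr8, and no coordinates were used, since the builds differ. Mature sequences were not used here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.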

Results

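The series asked which miRNAs change in cultured rat cortical neurons when Staufen2 is depleted. It measured small RNA in 4 libraries each of neurons with a non-targeting shRNA, with an shRNA against Stau2, and with an shRNA against Pum2. The shPum2 group served as a further control for changes that any active shRNA brings. Total counts were 4663807 ± 705700 per library in shNTC, 4553213 ± 393500 in shStau2 and 4444066 ± 490900 in shPum2 (SD, n = 4). The groups did not differ detectably in total (exact permutation p = 0.83 for shStau2 against shNTC, 0.686 for shPum2 against shNTC and 0.629 for shStau2 against shPum2; adjusted p = 0.994 for each among 18 depth tests; smallest possible p 0.0286). The mRNAs of Stau2 and Pum2 are not part of these small RNA tables, so the depletion itself was not analysed here.

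MiRNAs known from neurons made up much of the libraries. The most abundant miRNA was miR-9a-5p, which is made in neural progenitors and neurons, at 189440 ± 15040 CPM in shNTC, 190450 ± 15120 in shStau2 and 191250 ± 20250 in shPum2. It was followed by miR-125b-5p, the mammalian relative of worm lin-4, miR-128-3p, a miRNA of mature neurons, let-7c-5p, and miR-9a-3p, the partner strand of miR-9a-5p. These 5 miRNAs took 51.1 to 54.3% of the miRNA counts of a library. The neuronal miR-128-3p stood at 88700 ± 7309 CPM in shNTC, 95094 ± 5420 in shStau2 and 89959 ± 10680 in shPum2, and let-7c-5p at 73972 ± 8467, 76509 ± 7145 and 74386 ± 1982 CPM. For miR-9a-3p the levels were 39224 ± 3063, 38552 ± 3769 and 36643 ± 4629 CPM. None of these 4 passed the test in any comparison, and neither did miR-124-3p, a miRNA largely specific to neurons, with 4862 ± 629 CPM in shNTC, 5458 ± 361 in shStau2 and 4979 ± 229 in shPum2. The fifth, miR-125b-5p, passed with the replicate block and is described with shStau2.

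The comparison of shStau2 with shNTC asked what Stau2 depletion changed, and its leading answer was the miR-29 family, whose members increase as neurons mature and are known to repress pro-apoptotic mRNAs. The guide strand miR-29b-3p fell from 1480 ± 142 CPM in shNTC to 662 ± 121 CPM in shStau2, a log2 fold change of -1.16 (SE 0.19, adjusted p = 0.00911). The strand miR-29a-5p fell from 18.6 ± 2.29 to 7.46 ± 1.63 CPM, a log2 fold change of -1.31 (SE 0.20, adjusted p = 0.00423). Both were lower in 4 of 4 pairs of libraries with the same replicate number. These were the only 2 of 628 miRNAs past the threshold in edgeR's test without a block, 0 higher and 2 lower, while 71 had an unadjusted p under 0.05 against 31.4 expected by chance. Without shStau2 replicate 3, miR-29b-3p no longer passed (adjusted p = 0.0697) and 1 miRNA remained.

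**Figure D1:**
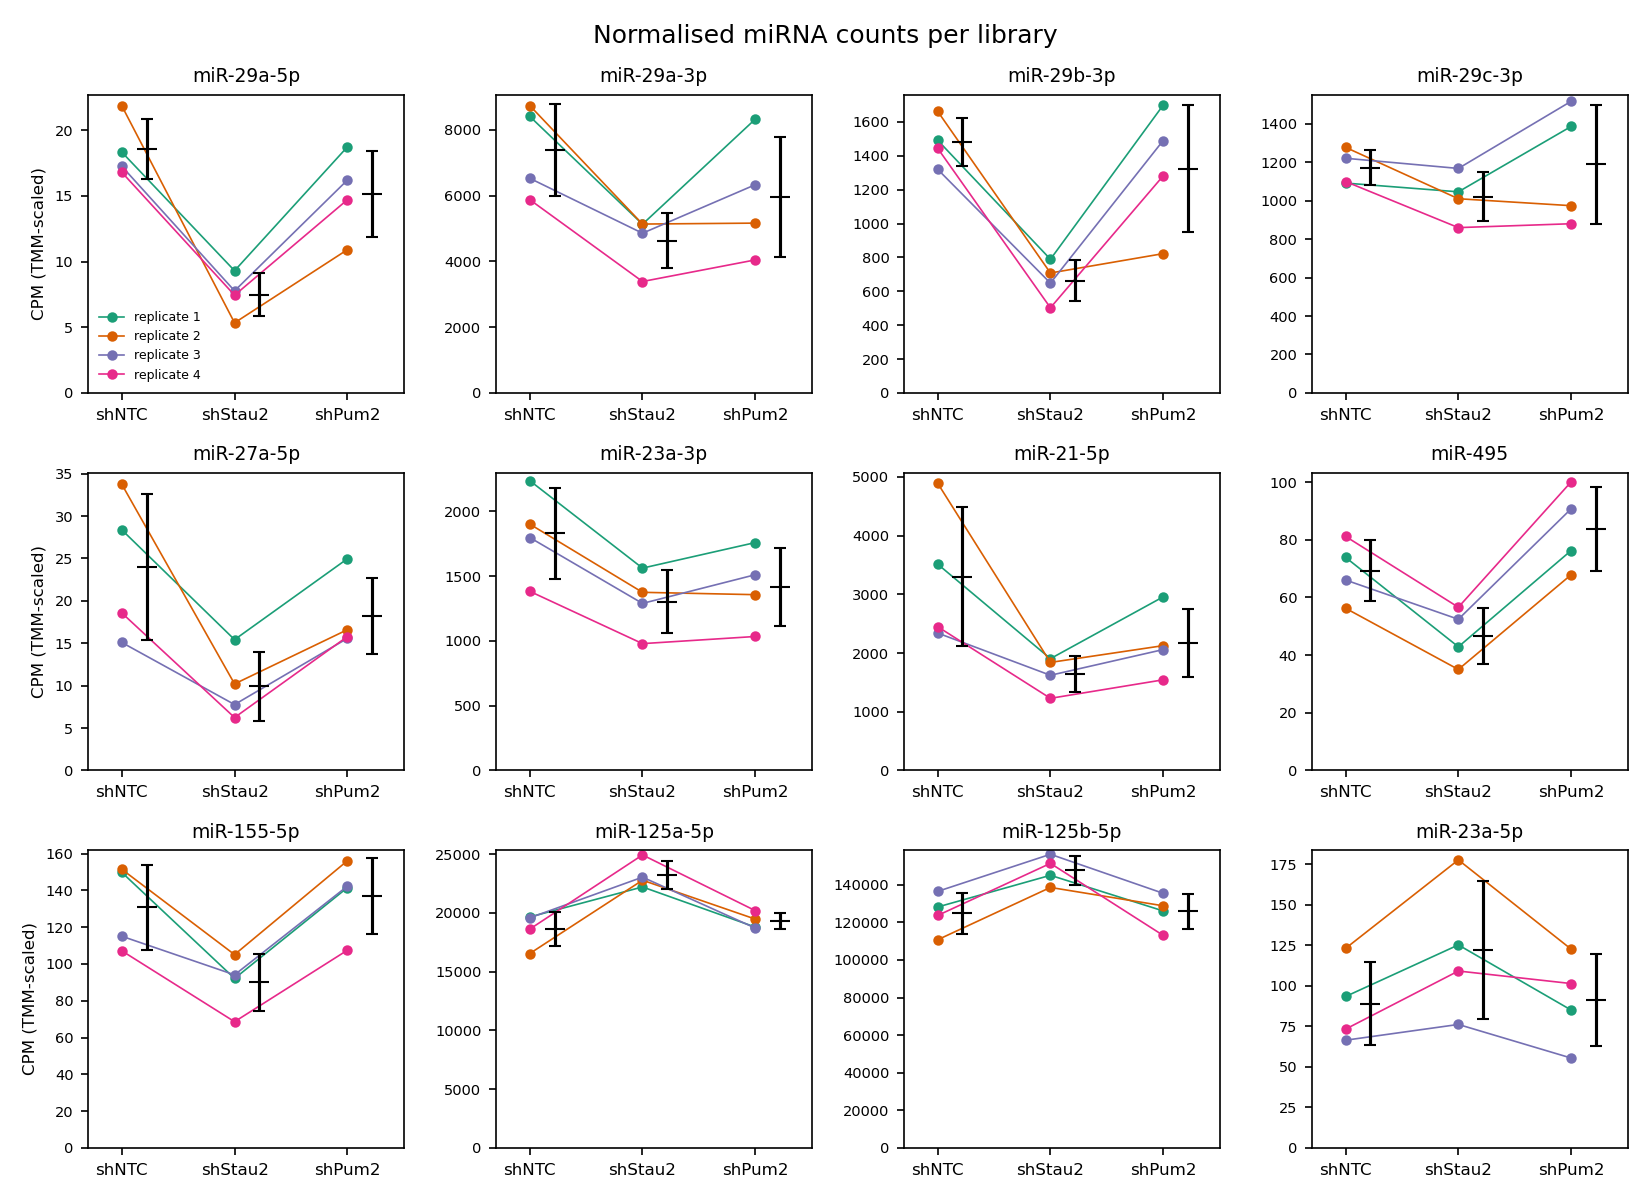
TMM-scaled CPM of 12 named miRNAs in each of the 12 libraries, by group, with points coloured by replicate number and joined across groups, and black bars for mean ± SD (n = 4). The level of miR-29b-3p averages 662 CPM in shStau2 against 1480 in shNTC and 1320 in shPum2.

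With the replicate block, 39 miRNAs passed in shStau2 against shNTC, 15 higher and 24 lower, and 141 had an unadjusted p under 0.05. More of the miR-29 family was among them: miR-29a-3p, its most abundant member, fell from 7389 ± 1402 to 4628 ± 837 CPM (log2 fold change -0.68, SE 0.11, adjusted p = 0.00374), and miR-29b-5p fell by 0.37 on the log2 scale (adjusted p = 0.0337). The miR-29c strands differed less: miR-29c-3p had a log2 fold change of -0.21 (adjusted p = 0.25) and miR-29c-5p of -0.17 (adjusted p = 0.324), neither past the threshold. In the table of assembly GRCr8 the gene Mir29a neighbours Mir29b1 with 1 gene between, and Mir29b2 neighbours Mir29c likewise. The mature miR-29b-3p comes from both loci.

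With the block, 5 of the 14 members of the astrocyte list fell and 1 rose. In the blood or microglia list 1 of 12 members fell, and in the vessel or mesenchyme list 1 of 14. Neither of these 2 lists passed as a whole (camera adjusted p = 0.457 and 0.359 with the block). The most abundant miRNA among those that fell was miR-21-5p, a miRNA of astrocytes and of many dividing cells, at 3298 ± 1187 CPM in shNTC and 1648 ± 305 in shStau2 (log2 fold change -0.97, SE 0.15, adjusted p = 0.00441). Its partner strand miR-21-3p fell by 1.18 on the log2 scale (adjusted p = 0.00994). From a shared primary transcript, miR-23a-3p fell from 1830 ± 352 to 1301 ± 243 CPM (log2 fold change -0.49, SE 0.07, adjusted p = 0.000178), miR-27a-3p from 526 ± 5.28 to 373 ± 51.8 CPM (-0.51, SE 0.11, adjusted p = 0.0146), and miR-27a-5p from 23.9 ± 8.62 to 9.91 ± 4.03 CPM (-1.27, SE 0.17, adjusted p = 0.000178). The opposite strand miR-23a-5p rose from 89.1 ± 25.4 to 122 ± 42.3 CPM (0.43, SE 0.10, adjusted p = 0.0186). The immune-cell miRNA miR-155-5p fell by 0.54 (adjusted p = 0.00119) and the endothelial miR-126a-5p by 0.46 (adjusted p = 0.0103) on the log2 scale.

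Among the miRNAs that rose with the block, miR-125b-5p went from 124760 ± 10750 to 147800 ± 7667 CPM (log2 fold change 0.25, SE 0.06, adjusted p = 0.0147) and its close relative miR-125a-5p from 18594 ± 1450 to 23236 ± 1181 CPM (0.32, SE 0.06, adjusted p = 0.0038). The strands miR-296-3p (0.46, adjusted p = 0.0157) and miR-296-5p (0.36, adjusted p = 0.033) of the imprinted Gnas locus rose, as did miR-298-5p (0.35, adjusted p = 0.0379) from the same locus, miR-185-3p (0.46, adjusted p = 0.0144) and miR-672-3p (0.38, adjusted p = 0.0239). The strands miR-344b-1-3p (0.33), miR-532-3p (0.46), miR-501-5p (0.45) and miR-3588 (0.24) rose as well. Of the 12 decreases with the smallest p, those not yet named were miR-495 (-0.58, adjusted p = 0.00119), miR-3587 (-0.73, adjusted p = 0.00119) and miR-543-3p (-0.42, adjusted p = 0.0144). The count with the block depended on single replicate numbers, with 23 calls without number 1, 23 without number 2 and 5 without number 4, and DESeq2 called 18 without a block and 38 with it. With scaling to library totals within the block the split was 7 higher and 32 lower in place of 15 and 24.

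Among the fixed lists, the miR-29 family stood lower in shStau2 than in shNTC (camera adjusted p = 1.06e-06, 6 members, median log2 fold change -0.52), a call lost with the estimated correlation (adjusted p = 0.174 with an estimated correlation). Of its members 2 fell over all miRNAs tested, 4 fell adjusted over the list alone, and 4 fell with the block. The Dlk1-Dio3 cluster, an imprinted group expressed in neurons from the maternal chromosome, stood lower by little (adjusted p = 0.00228, 85 members, median -0.08), and this call was lost too (adjusted p = 0.174 with an estimated correlation). Of its members 0 passed in edgeR's test without the block, over all miRNAs or adjusted over the list alone, and 5 fell with the block: miR-495, miR-758-3p (-0.48), miR-543-3p, miR-380-3p (-0.41) and miR-409b (-0.25). Its most abundant members stood level or higher, miR-127-3p at 0.15 and miR-382-5p at 0.04, neither past the threshold. The astrocyte list also stood lower (adjusted p = 0.00234, 14 members, median -0.10), again not with the estimated correlation (adjusted p = 0.546 with an estimated correlation). Of its members 0 passed over all miRNAs, 5 fell adjusted over the list alone, and with the block 5 fell (both strands of miR-21 and miR-27a, and miR-23a-3p) and 1 rose (miR-23a-5p). The other 8 members did not pass, the most abundant of them miR-24-3p at -0.14.

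With the directional test of fry, which does not compare a list with other miRNAs, only the miR-29 family passed without the block (adjusted p = 0.027). With the block 4 lists did: the miR-29 family (fry adjusted p = 0.00895), the Dlk1-Dio3 cluster (0.0337), the astrocyte list (0.032) and the decay list (0.032). The mixed test of fry, which asks whether members differ in either direction, passed for 5 lists without the block (the miR-29 family, the Dlk1-Dio3 cluster, and the astrocyte, decay and activity or dendrite lists, the last with adjusted p = 0.0386) and for 8 with it. Without shNTC replicate 4 the Dlk1-Dio3 call ended (camera adjusted p = 0.0597).

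The lists of neuronal identity did not pass with camera in shStau2 against shNTC. Of the 24 neuron-enriched miRNAs 0 passed in edgeR's test with or without the block (camera adjusted p = 0.742, median log2 fold change 0.00). Of the 12 activity or dendrite miRNAs, which include miR-125b-5p, 1 rose with the block (camera adjusted p = 0.742). Of the 20 let-7 members only let-7i-5p fell, by 0.20 with the block (camera adjusted p = 0.325), and of the 24 members of the miR-17 cluster and its paralogs only miR-17-5p, by 0.31 (camera adjusted p = 0.802). For the other families the camera adjusted p was 0.896 for the miR-183, miR-96 and miR-182 cluster, 0.948 for the miR-200 family, 0.604 for the miR-30 family and 0.742 for the miR-181 family. It was 0.863 for the p53-responsive miRNAs, 0.325 for the decay list, in which miR-29b-3p fell, and 0.15 for the miRNAs that bypass Drosha or Dicer. Markers of further cell types gave 0.742 for oligodendrocytes, 0.663 for blood or microglia, where 1 of 12 fell adjusted over the list alone (miR-155-5p), 0.325 for vessels or mesenchyme, where 1 of 14 did (miR-126a-5p), and 0.742 for choroid or ciliated cells, where miR-204-3p rose by 0.75 with the block.

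**Figure D2:**
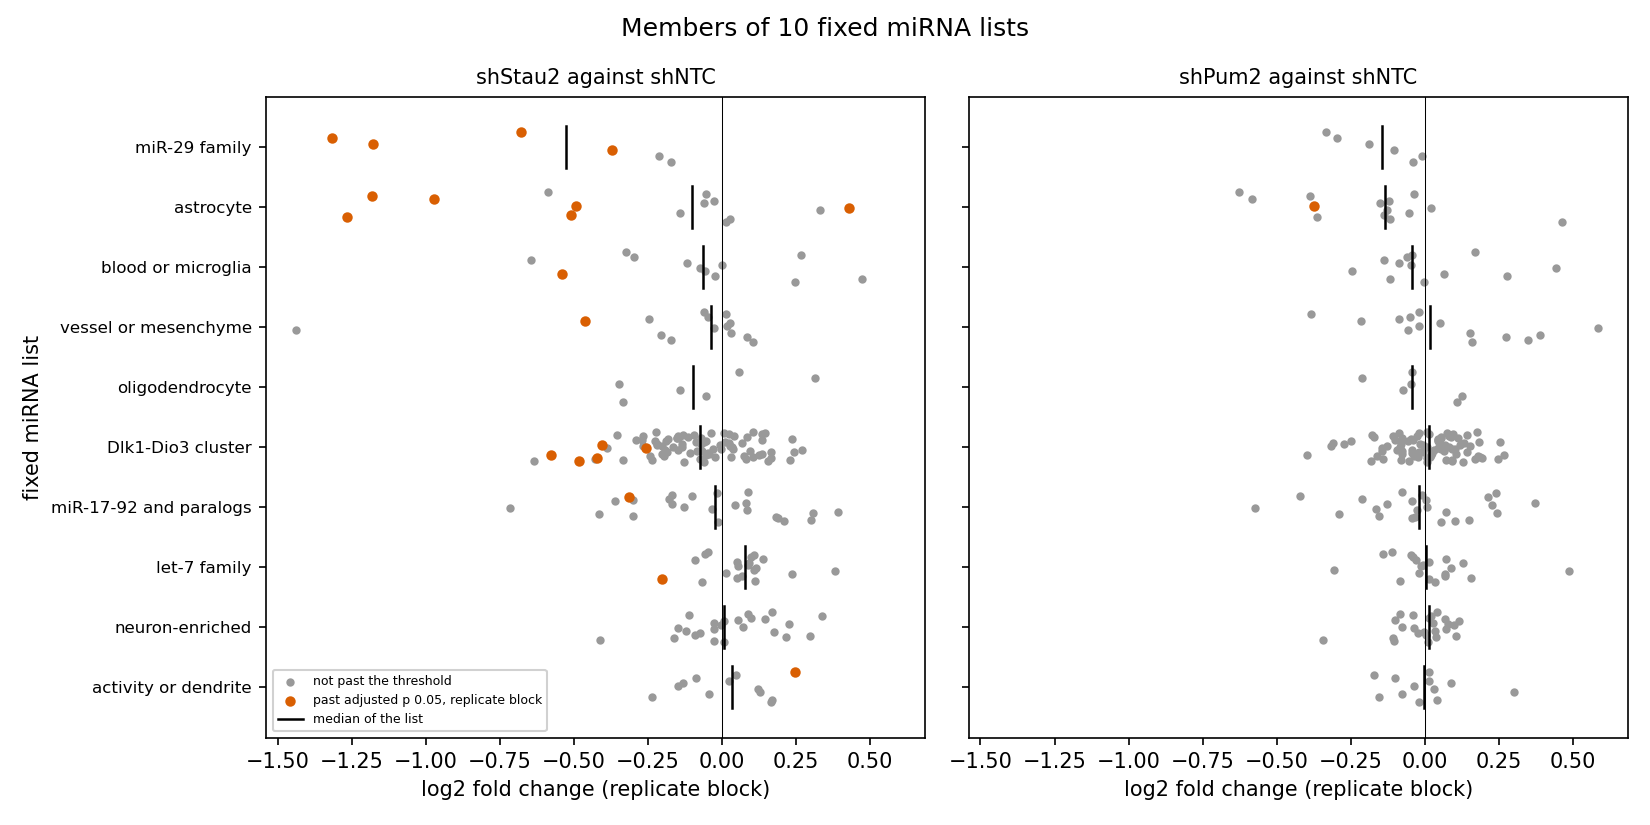
Log2 fold changes with the replicate block for the members of 10 fixed lists, with a point per miRNA. The panels show shStau2 minus shNTC and shPum2 minus shNTC, which share the shNTC libraries. The miR-29 family has a median of -0.53 in the first panel and -0.14 in the second, and the neuron-enriched miRNAs lie around 0.

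The comparison of shPum2 with shNTC asked what another active shRNA changed. No miRNA passed in edgeR's test without a block (0 of 628, smallest adjusted p = 0.982), 9 had an unadjusted p under 0.05 against 31.4 expected by chance, and DESeq2 called 0. The miR-29 members that were lower in shStau2 had values of -0.16 for miR-29b-3p and -0.29 for miR-29a-5p, not past the threshold. The smallest unadjusted p belonged to miR-6318 (-0.64, 5.10 ± 1.76 against 7.90 ± 1.2 CPM), miR-33-5p (0.57), miR-181b-1-3p (-0.45), miR-881-3p (-0.68) and miR-471-5p (-0.98), with adjusted p = 0.982 for each. With the replicate block 1 miRNA passed, miR-23a-3p, which fell from 1830 ± 352 to 1415 ± 303 CPM (log2 fold change -0.37, SE 0.07, adjusted p = 0.0179, lower in 4 of 4 pairs), and 46 had an unadjusted p under 0.05. It did not pass in any of the 4 fits that left out a replicate number: 0 miRNAs were called without number 1, 3 or 4, and 2 others without number 2.

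In shPum2 against shNTC the astrocyte list stood lower (camera adjusted p = 0.0138, median -0.13), although 0 of its 14 members passed without the block, over all miRNAs or adjusted over the list alone. It had adjusted p = 0.948 with an estimated correlation, and the call ended without shNTC replicate 2 (camera adjusted p = 0.206), shPum2 replicate 2 (0.128) or shPum2 replicate 4 (0.32). Its member miR-21-5p stood at 2171 ± 585 CPM against 3298 ± 1187, a log2 fold change of -0.58 with the block (adjusted p = 0.388). With the block the cluster of miR-183, miR-96 and miR-182, miRNAs of sensory cells, stood higher (camera adjusted p = 0.0467; adjusted p = 0.663 with an estimated correlation). Without the block it did not pass (camera adjusted p = 0.316), but did without shPum2 replicate 3 (0.00216), as it did, lower, in shStau2 against shPum2 without that library (0.0111, against 0.606 with it). Its member miR-183-5p stood at 323 ± 188 CPM against 223 ± 70.6 CPM (adjusted p = 0.663). The remaining 17 lists did not pass with camera without the block, and with fry 0 passed in either test, with or without the block. Among them the miR-29 family had camera adjusted p = 0.152 (0.0563 with the block), and it passed without shPum2 replicate 1 (camera adjusted p = 0.00407) and without shPum2 replicate 3 (0.0281).

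The comparison of shStau2 with shPum2 used the control that also carried an active shRNA. Again miR-29b-3p fell, from 1320 ± 375 to 662 ± 121 CPM (log2 fold change -1.0, SE 0.19, adjusted p = 0.0349), and miR-29a-5p from 15.1 ± 3.27 to 7.46 ± 1.63 CPM (-1.02, SE 0.20, adjusted p = 0.0349). The Dlk1-Dio3 member miR-495 fell from 83.8 ± 14.4 to 46.7 ± 9.70 CPM (-0.84, SE 0.17, adjusted p = 0.0349). All 3 were lower in 4 of 4 pairs, and no other miRNA passed in edgeR's test without a block, where 59 had an unadjusted p under 0.05. The 3 calls sat close to the threshold: 0 were left with upper-quartile factors, in a fit of the 8 libraries, or without shNTC replicate 1 or 3, shStau2 replicate 2, 3 or 4, or shPum2 replicate 1, 3 or 4, while DESeq2 called 7.

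With the block, 25 miRNAs passed in shStau2 against shPum2, 10 higher and 15 lower, and 124 had an unadjusted p under 0.05. The smallest p belonged to miR-495 (log2 fold change -0.85, SE 0.10, adjusted p = 2.25e-05). Other decreases were those of miR-155-5p (-0.61, adjusted p = 0.000697), miR-17-5p of the proliferation-linked miR-17 cluster (-0.52, adjusted p = 0.00151), the Dlk1-Dio3 members miR-380-3p (-0.53, adjusted p = 0.00334) and miR-543-3p (-0.43, adjusted p = 0.0197), the muscle miRNA miR-206-3p (-0.52, adjusted p = 0.00704), miR-27a-5p (-0.90, adjusted p = 0.00775), miR-3068-5p (-0.40), miR-409b (-0.30) and miR-151-5p (-0.34). The blood-cell miRNA miR-142-3p fell by 0.49 (adjusted p = 0.0388). Increases were those of miR-185-3p (0.46), miR-125a-5p (0.27), miR-878 (0.65), miR-125b-5p (0.23), miR-15b-5p (0.38), miR-23a-5p (0.41), miR-344b-1-3p (0.36), miR-434-3p (0.24), miR-3542 (0.46) and miR-7a-5p (0.24), a neuronal and neuroendocrine miRNA that rose from 11979 ± 923 to 14178 ± 1754 CPM (adjusted p = 0.0349). Of the 6 miR-29 members only 2 passed with the block, miR-29a-5p and miR-29b-3p. The most abundant member, miR-29a-3p, did not pass, at 4628 ± 837 CPM in shStau2 against 5967 ± 1829 in shPum2. For miR-21-5p the difference was -0.39 (adjusted p = 0.176) and for miR-23a-3p -0.12 (adjusted p = 0.357), neither past the threshold. The count was 6 without replicate number 1, 51 without number 2, 7 without number 3 and 10 without number 4, and upper-quartile factors within the block gave 26 higher and 14 lower in place of 10 and 15.

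Of the lists, the miR-29 family (camera adjusted p = 9.79e-05, median -0.32; 2 members fell over all miRNAs and 2 adjusted over the list alone) and the Dlk1-Dio3 cluster (adjusted p = 0.000182, median -0.08; 1 member fell over all miRNAs and 2 adjusted over the list alone) stood lower in shStau2 than in shPum2. The 2 lists had adjusted p = 0.261 and adjusted p = 0.162 with an estimated correlation. With the block 4 Dlk1-Dio3 members fell (miR-495, miR-380-3p, miR-543-3p and miR-409b) and 1 rose (miR-434-3p). With the directional test of fry 0 lists passed without the block, and 4 with it: the miR-29 family, the Dlk1-Dio3 cluster, the decay list and the blood or microglia list (fry adjusted p = 0.0385 for each). The mixed test of fry passed for 2 lists without the block, the Dlk1-Dio3 cluster (adjusted p = 0.0153) and the activity or dendrite list (0.0324), and for 11 with it. The astrocyte list did not pass here with camera (camera adjusted p = 0.364). With the block the vessel or mesenchyme list stood lower as well (camera adjusted p = 0.0436; adjusted p = 0.185 with an estimated correlation), and of its 14 members miR-206-3p fell. The neuron-enriched list had camera adjusted p = 0.606 with 0 members past the threshold in edgeR's test.

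Calls against both controls answered the question of the design most directly. Without a block they were miR-29a-5p and miR-29b-3p, 0 higher and 2 lower, where independent lists would share 0.00955 lower. With the block they were 17, 5 higher and 12 lower, where independent lists would share 0.239 higher and 0.573 lower. Simulated unchanged groups that shared the libraries in the same way gave 0 in 50 simulations with either fit. These drew each miRNA independently and so lack structure of the real libraries, of which other groupings reached 6 without the block and 17 with it. The grouping with 17 may be one that only exchanged the controls, which was not checked. The 5 higher were miR-125a-5p, miR-125b-5p, miR-185-3p, miR-23a-5p and miR-344b-1-3p. The 12 lower were miR-29a-5p, miR-29b-3p, miR-27a-5p, miR-155-5p, miR-17-5p, let-7i-5p, miR-455-3p, miR-3068-5p and the Dlk1-Dio3 members miR-495, miR-543-3p, miR-380-3p and miR-409b. Without the block the count was 0 without shNTC replicate 1 or 3, shStau2 replicate 2, 3 or 4, or shPum2 replicate 1, 3 or 4, and 1 without shNTC replicate 4. With the block it was 4 without replicate number 1, 5 without number 3 and 3 without number 4.

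Across the 628 miRNAs, which are not independent replicates, the fold changes of shStau2 against shNTC and against shPum2 had r = 0.76, where simulated unchanged groups that shared the shStau2 libraries gave 0.50. Their covariance was 0.0638 against 0.0168 simulated. With the shStau2 libraries split between the comparisons, r had a median of 0.301 (0.243 to 0.551 over 6 ways). For shStau2 and shPum2 each against shNTC, r was 0.34 against 0.48 simulated, the covariance 0.0197 against 0.0159 simulated (SD 0.00234), and with the shNTC libraries split r had a median of 0.0506 (-0.23 to 0.228).

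**Figure D3:**
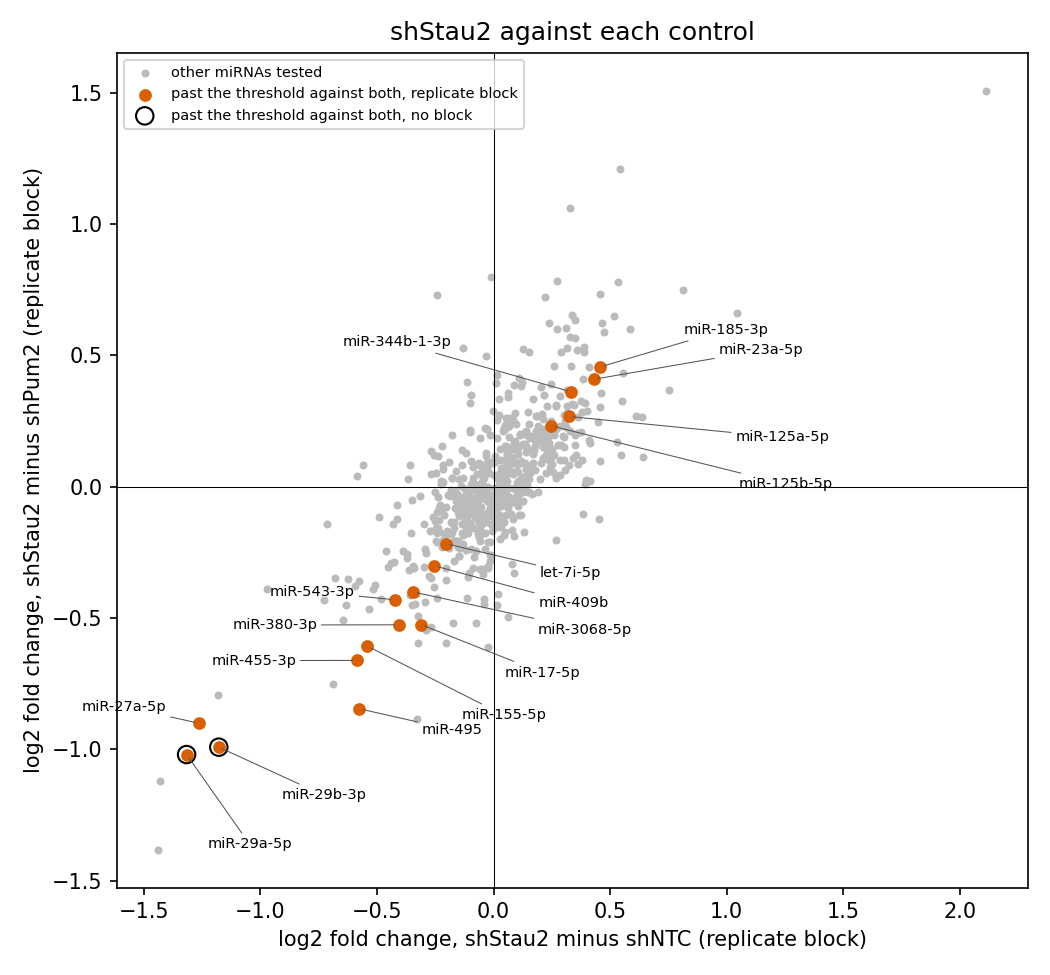
Log2 fold change with the replicate block of each of 628 miRNAs in shStau2 minus shNTC (horizontal) and shStau2 minus shPum2 (vertical), with the 17 miRNAs past the threshold against both controls in orange and the 2 that also passed without a block circled. Both axes share the shStau2 libraries, and miR-29a-5p and miR-29b-3p lie at the lower left.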

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

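All tests in this part were chosen after the results were seen, apart from the comparisons of library values. Of 222 groups of 4 libraries, from 73 named miRNAs and the total counts in each of the 3 groups, 13 had a library far from the other 3 (5.86%), where chance gives about 5%, and they fell in 10 libraries. The values below are CPM of that library against the range of the other 3, and no explanation was tested for them.

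Among miRNAs named for shStau2, miR-29a-3p stood at 3388 in shStau2 replicate 4 (others 4857 to 5136), on the side of the group difference. For miR-27a-5p, shPum2 replicate 1 had 25.0 (others 15.6 to 16.6). The imprinted miR-298-5p stood at 957 in shNTC replicate 2 (others 1184 to 1213), miR-434-3p at 5120 in shNTC replicate 1 (others 4040 to 4171), and miR-878 at 16.7 in shNTC replicate 2 (others 8.67 to 9.02). The abundant miR-9a-5p reached 221400 in shPum2 replicate 3 (others 178600 to 184000), and miR-30d-5p stood at 7173 in shStau2 replicate 1 (others 7561 to 7601). In replicate 2, the p53-responsive miR-192-5p was high in shStau2 at 315.9 (others 268.9 to 276.1) and in shPum2 at 299.0 (others 275 to 279). Also in shPum2 replicate 2, the choroid plexus miRNA miR-204-5p reached 1893 (others 1273 to 1368) and the endothelial miR-126a-3p stood at 367 (others 401 to 403). For the sparse miR-881-3p shNTC replicate 4 had 3.56 (others 6.31 to 6.71), and for miR-181b-1-3p shNTC replicate 3 had 14.5 (others 10.6 to 11.04).

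The piRNA names lie outside the miRNA comparisons, and took 0.684 to 0.989% of the counts of a library. Of 90 tested, 0 passed without a block in any comparison in edgeR's test (1, 5 and 6 had an unadjusted p under 0.05 in shStau2 against shNTC, shPum2 against shNTC and shStau2 against shPum2; DESeq2 was not run on them). With the block 2, 1 and 4 passed. The name piR_009003 was higher than in shNTC in both knockdowns, by 0.39 in shStau2 (adjusted p = 0.0266) and 0.60 in shPum2 (adjusted p = 0.00404) on the log2 scale. The name piR_028761 was higher in shStau2 than in shNTC by 0.49 (adjusted p = 0.0266) and than in shPum2 by 0.90 (adjusted p = 0.000423). In shStau2 against shPum2, piR_000219 differed by -0.43, piR_012452 by -0.63 and piR_019073 by -0.97. Whether these counts come from piRNAs or from fragments of other RNAs was not tested.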

How the results depend on the processing

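The alternatives within the replicate block were chosen after seeing the data, and the others were planned. Over 56 fold changes of named miRNAs, 1180 of 1282 alternative values kept their direction and side of the threshold, 33 no longer passed, 69 newly passed (42 with the block, 17 with DESeq2) and 0 reversed. In shStau2 against shNTC, miR-29a-5p passed in 23 of 23 settings (log2 fold change -1.44 to -1.18) and miR-29b-3p in 22 of 23 (-1.26 to -1.05). In shStau2 against shPum2, miR-29a-5p passed in 13, and miR-29b-3p and miR-495 in 12 of 23. No miRNA or list called without the block was lost with it. The cause of the changes below was not tested, except that leave-outs have fewer samples. Another scaling moved the median of all miRNAs by at most -0.06. Small changes were often missed in simulation. For shStau2 against shNTC, with 200 miRNAs changed, 11.8% of the smallest seeded changes were recovered without the block and 45.5% with it. What set this limit was not tested.

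Counts of miRNAs in shStau2 against shNTC (2) were 18 with DESeq2, 39 with the replicate block, 5 at an adjusted p of 0.1, and 1 to 3 with a library left out. With the block, 68 passed in a fit of 8 libraries, and 5 to 27 without a replicate number (23, 23 and 5 without numbers 1, 2 and 4). In shPum2 against shNTC (0) the block gave 1 and leaving out a library 0. Within the block DESeq2 gave 2, the 8 libraries 0, and leaving out a number 0 to 2. In shStau2 against shPum2 (3) upper-quartile factors gave 0, DESeq2 7, the block 25, the 8 libraries 0, and leaving out a library 0 to 4. Within the block upper-quartile factors gave 40, the 8 libraries 80, and leaving out a number 6, 51, 7 and 10. Calls against both controls (2) were 0 with upper-quartile factors, 7 with DESeq2, 17 with the block and 0 to 2 with a library left out. With the block they were 3 to 20 without a number (4, 5 and 3 without numbers 1, 3 and 4).

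Lists past the threshold were 0 with an estimated correlation in all 3 comparisons, and with the directional test of fry 1 in shStau2 against shNTC (3 with camera), 0 in shPum2 against shNTC (1) and 0 in shStau2 against shPum2 (2). With the block it gave 4, 0 and 4, and the mixed test 5, 0 and 2 without the block and 8, 0 and 11 with it. With camera the block gave 2 in shPum2 against shNTC, and leaving out a library there 0 to 4.

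The difference in mean total counts was -110594 in shStau2 against shNTC (-386413 to 140058 with a library left out), -219741 in shPum2 against shNTC (-495560 to 30911) and 109147 in shStau2 against shPum2 (-84458 to 336606). It reversed to 17734 and 140058 without shNTC replicates 1 and 3, to 30911 without shNTC replicate 3, and to -84458 and -39625 without shStau2 replicate 3 and shPum2 replicate 2. None of these differences passed an exact permutation test.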

Other observations

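The tests in this part were chosen after the results were seen. Both strands of a hairpin give a further view of the miRNAs that moved. With the block, shStau2 against shNTC had 6 hairpins with both strands past the threshold and at 10 CPM or more (both strands of miR-21 also fell, with miR-21-3p at 5.52 CPM). In 5 of the 6 both strands moved in the same direction: miR-29a, miR-29b, miR-27a and miR-455 fell (miR-455-5p by 0.58 and miR-455-3p by 0.59 on the log2 scale) and miR-296 rose. In the other, miR-23a, the strands moved apart. Across 127 hairpins with both strands at 10 CPM or more, the fold changes of the strands had r = 0.41 (Spearman's rho 0.27, permutation p = 3e-05, 100000 resamples). Without the 2 hairpins whose 5p strands lay farthest from the 5p median, miR-29a and miR-27a, r was 0.28. The 3p strands were not used for this choice, so miR-29b with its 3p strand at -1.18 stayed in. Hairpins were counted by miRNA name, which can pool several loci as for miR-29b, and are not independent replicates. In shPum2 against shNTC r was 0.29 (permutation p = 8e-04) and in shStau2 against shPum2 0.38 (permutation p = 3e-05), so strands also varied together in a comparison with 1 called miRNA. A candidate explanation is that the strands share part of their variation through the amount of the hairpin or of the cells that make it (r = 0.41). Noise in the fold changes lowers r, and how much of the variation is not shared was not tested.

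Lower miR-29a and miR-29b in shStau2 were weighed first. Reads passed between miR-29 members would leave their sum unchanged. However, the summed counts of miR-29a-3p, miR-29b-3p and miR-29c-3p had a log2 fold change of -0.68 (SE 0.121, adjusted p = 0.0108). Each strand was already lower by itself (-0.68, -1.18 and -0.21 in that order), so the sum repeats those values and is not a separate test. Whether exchange shaped how the fall divided between the members was not tested. A trend with base composition would move miR-29a-3p and miR-29c-3p nearly alike, since their known sequences differ at a single base, but their log2 ratio changed by -0.47 (SD 0.125 over 4 pairs, exact permutation p = 0.0286 for 4 against 4 libraries, the smallest possible), which argues against such a trend as the whole cause. Fewer astrocytes in the shStau2 cultures stay open. The median of the 14 astrocyte miRNAs was -0.10 (SD 0.531), with miR-21-5p at -0.97, miR-24-3p at -0.14 and miR-23a-5p at 0.43. The members go in different directions and decide nothing. In shPum2 against shNTC the list median was -0.13 with the block, and no miR-29 strand passed. In shStau2 against shPum2 the list median was -0.05 with the block (camera adjusted p = 0.262), with 8 members below 0 and 6 above. There miR-29b-3p and miR-29a-5p still fell (-0.99 and -1.02), and so did the astrocyte-list miR-27a-5p (-0.90). These values do not settle the explanation. An effect of Stau2 depletion, or of the shRNA on other targets, may also account for the difference and was not separable here, since a single shRNA was used and Stau2 mRNA was not measured.

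Lower miR-23a-3p with higher miR-23a-5p in shStau2 was weighed next. Reads exchanged with the near-identical miR-23b-3p would leave the sum unchanged, but the summed counts of miR-23a-3p and miR-23b-3p had a log2 fold change of -0.27 (SE 0.0628, adjusted p = 0.0143). Less of the transcript, or of the cells that make it, stays open for the lower miR-23a-3p: miR-27a-3p and miR-27a-5p of the same transcript fell too (-0.51 and -1.27), while the rise of miR-23a-5p (0.43) would need a further cause. No further strand of the transcript was weighed, and how much of miR-24-3p comes from this transcript was not tested. The astrocyte-list miRNA miR-24-3p went from 2422 ± 147 CPM in shNTC to 2193 ± 40.2 in shStau2 and did not pass. The lower miR-23a-3p was also seen in shPum2 against shNTC (-0.37, adjusted p = 0.0179), and shStau2 and shPum2 did not differ detectably in it (-0.12, adjusted p = 0.357). Both comparisons with shNTC share its libraries, and the shPum2 call passed in 0 of the 4 fits that left out a replicate number. A change in which strand is kept, or in the stability of a strand, remains a hypothesis that could be followed up, and it rests on the block, where miR-23a-5p passed in 12 of 15 settings and in 1 of the 4 that left out a replicate number.

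The lower Dlk1-Dio3 cluster was weighed last. A cluster lowered as a whole by the same amount would leave fold changes that scatter by their standard errors, but their variance was 3.02 times that in shStau2 against shNTC (weighted mean -0.07) and 1.43 times in shPum2 against shNTC. Noise of the less abundant members stays open: the 46 members under 100 CPM had a median of -0.11 (camera p = 0.00636; p = 0.052 with an estimated correlation) and the 39 at or above it -0.06 (camera p = 0.0339; p = 0.204 with an estimated correlation). A change in some members, such as miR-495, miR-543-3p and miR-380-3p, may fit better than a change of the cluster (3.02), as a hypothesis from the same data.

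Other splits of the libraries show how far chance could account for the counts. In shStau2 against shNTC the 2 miRNAs were matched by 1 of 35 splits, the real one, with 0 at most in the others. That share is under 0.05 and is the smallest that 35 splits can give. The 35 splits ignore the pairing. Of them 8 part every pair, and none of the other 7 matched the real 2 (0 at most). These 8 are too few for a share under 0.05, so chance is not excluded once the pairing is kept. In shStau2 against shPum2 2 of 35 splits gave as many as the real 3, and the highest other gave 16; chance is not excluded there. That split set replicates 1 and 3 of both groups against 2 and 4, so it followed a structure of the replicate numbers. Among the 7 other splits that part the pairs as the real one does the highest was 0, and the blocked count is 25. In shPum2 against shNTC 35 of 35 splits gave at least the real 0, with 1 at most. With the block each comparison has 8 splits, too few for a share under 0.05: the real counts were 39 (highest other 0; 1 split as large), 1 (highest other 32; 2 splits as large) and 25 (highest other 0; 1 split as large) in shStau2 against shNTC, shPum2 against shNTC and shStau2 against shPum2. The 32 came from shNTC replicates 1 and 3 with shPum2 replicates 2 and 4 set against the rest, many times the real count, which points to a structure among the numbers that the block leaves in.

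For calls against both controls, 3 of 100 drawn splits gave as many as the real 2 (highest 6). Of 100 drawn relabellings within replicate numbers, 2 gave as many as the real 17 (highest other 17). Both shares, which count the real grouping, were under 0.05. Other groupings still matched or passed the real count in each set, so chance was unlikely there but not excluded. The first set ignored the pairing of the libraries by number. The second did not leave out relabellings that only exchange shNTC and shPum2. Such an exchange throughout gives 17 by construction, and whether the match at 17 was of that kind was not checked. Chance cannot be excluded for the fixed lists: 15 of 35 splits gave at least the 3 lists of shStau2 against shNTC (highest other 8), 25 of 35 the 1 of shPum2 against shNTC (highest other 6), and 20 of 35 the 2 of shStau2 against shPum2 (highest other 6). With the block and 8 splits, too few for a share under 0.05, 2, 3 and 2 splits gave at least the real 3, 2 and 3 lists, with 3, 3 and 4 as the highest other.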
